A study of Homo sapiens with 18 samples.

How the data were processed

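The series holds 18 single-colour microarrays of total RNA from HL60 cells, and each has a scanner file and a column in a series matrix. Per the labels' protocols, the cells were infected with retroviral vectors, kept in 200 nM 4-hydroxytamoxifen for 16 h and then given 100 nM retinoic acid or ethanol for 4 h, and 500 ng of total RNA was labelled with Cy3. The series description speaks of independent experiments, and groups of 3 and 4 arrays are present here. Groups were taken from the sample titles: empty vector (n = 4), empty vector with retinoic acid (labelled RA, n = 4), MycD (n = 3), MycD with retinoic acid (n = 4) and MycA with retinoic acid (n = 3).

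Per the file headers, the scanner files were made with Agilent Feature Extraction 10.5.1.1 and give a fluorescence intensity for each spot, from which the software had subtracted background before the authors deposited them. The deposited series matrix holds log2 values that are the same in distribution on every array (median 7.88), as after quantile normalization. Its tool is not given in the sources used here. The ranks of its values followed the mean minus background intensity of the scanner files with a correlation of 0.999999. The series matrix was used as an alternative, and the background-subtracted intensity for the results reported. Further columns of the scanner files, such as the flags for outlying and saturated spots and for spots well above background, were used as filters.

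Each array has 45015 spots, of which 43376 are not controls, and 41000 distinct probes. Probes were named through their accessions in a table of human genes on assembly GRCh38 (25398 probes), the symbol in the array file (2510) or an older symbol (789), and 12303 had no name in that table and kept the array's own name. The table gave names only, and positions are those in the scanner files, on hg18. The values analysed were log2 of the intensity minus the log2 of the array's 75th percentile. Spots marked as outliers by the software (132 to 286 per array) were left out, and no spot was saturated. A probe was kept when it was well above background on every array of at least 1 group, which 27130 probes were. It also needed at least 2 usable arrays in each group, which removed 3 of these. The brightest probe stood for each gene, giving 19651 genes or unnamed transcripts. Arrays correlated at 0.9793 to 0.9941 with each other.

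Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 5 groups at once, two-sided, and with Benjamini-Hochberg adjusted p under 0.05 over all genes as the threshold. The 6 comparisons were retinoic acid in empty vector cells, retinoic acid in MycD cells, MycD against empty vector without and with retinoic acid, MycA against empty vector with retinoic acid, and MycD against MycA with retinoic acid. The interaction of MycD with retinoic acid was a further contrast. Where a group's arrays were all not well above background, the fold is given as at least the ratio to its signals, each replaced by the lowest signal marked well above background on that array where that was higher. The tests, the alternatives listed below, the rule for naming genes and the gene lists were set before the data were examined. The rule named, per comparison, the 10 genes with a symbol that rose most and the 10 that fell most among those past the threshold with no overlap between the groups' values, and members of the gene lists, MYC, RARA, RARB and PAK2 could also be named. Genes whose call held in the most settings were preferred among these.

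There were 25 gene lists, written from general knowledge: genes that respond to retinoic acid, retinoid receptors and coregulators, genes activated by Myc, genes repressed by Myc, ribosome biogenesis, cytosolic ribosomal proteins, neutrophil maturation, promyelocyte and primary granule genes, monocyte and macrophage genes, erythroid and megakaryocyte markers, lymphoid markers, stromal and epithelial markers, S phase, G2/M, p53 targets, the BCL2 family and apoptosis, the interferon response, NF-kappa-B and inflammatory genes, immediate early and stress genes, the unfolded protein and amino acid response, glycolysis and hypoxia, cholesterol synthesis, HOX genes, estrogen receptor targets, and adhesion and migration. They were tested with camera from limma, which compares a list with the other genes, at a preset correlation between genes of 0.01 and an adjusted p under 0.05 over the 25 lists. The retinoic acid list in both responses to it, and the HOX list in MycD cells with retinoic acid against either MycD cells or empty vector cells with retinoic acid and in the interaction, are the calls that held with an estimated correlation. Missing values (429, or 0.121%) were filled with the group mean for these tests. Counts adjusted over the list alone use the p-values of the list's members only.

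The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, probes well above background on all 18 arrays, the average of a gene's probes, slide as a fixed or random block, the replicate number of the title or of the sample description as a block, that number with slide, only the groups compared, array weights, the series matrix values, each array left out in turn, and for lists an estimated correlation and fry. Leaving out MycD replicates 1 and 2 together was added after the data were seen. The 18 arrays lay on 5 slides, which the array identifiers give, and each comparison had at least 2 slides with both groups. No scaling moved the median of all genes by more than 0.1 log2. The tests were checked on simulated values for 19651 genes with 200 of them changed and no slide effect. In the comparison of retinoic acid with empty vector 86.6% of the genes changed 2-fold and 61.2% of those changed 1.5-fold were recovered, with 85.1% and 59.7% in that of MycA with empty vector and 56.7% and 46.3% in the interaction, and no unshifted list was called. Between 4 and 11 unchanged genes were called per comparison. The adjusted threshold is stricter where fewer genes change. In the real data 6 genes passed for MycA and 2 for the interaction, so recovery there may be lower than in the simulation. The simulated genes were drawn independently of each other, so the check does not show how the list test behaves with correlated genes. Unnamed transcripts are counted in the totals and named only where the text says so, and control spots were left out.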

Results

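Gene expression was measured in HL60 cells, a human promyelocytic leukemia line that matures towards granulocytes when it is given retinoic acid. The cells carried a retroviral vector with an estrogen receptor tag, either empty or joined to a form of the transcription factor Myc called MycD or MycA. The ligand of the tag, 4-hydroxytamoxifen, was present in every sample. The series title speaks of a phosphomimetic Myc, and the labels do not say which residues MycD and MycA change. Total RNA was hybridised in a single colour to 18 Agilent whole-genome arrays in 5 groups. These were empty vector (n = 4), empty vector with retinoic acid (n = 4), MycD (n = 3), MycD with retinoic acid (n = 4) and MycA with retinoic acid (n = 3). The labels of the second group name only the treatment, and these cells are taken here as empty vector cells because the treatment protocol gives the empty vector as the control. The series design speaks of wild-type cells instead, and if that holds for this group, every comparison with it against another line also carries any effect of the vector. MycA cells without retinoic acid are not analysed here, so the response of MycA cells to retinoic acid could not be estimated. Each construct was carried by its own line of infected cells. A comparison between constructs therefore cannot tell an effect of MycD or MycA from other differences between the lines. Genes said below to change with or by MycD or MycA are genes that differ between these lines. Between 61.25% and 74.82% of the spots of an array were well above background, with the lowest shares on MycD replicates 2 and 1 (61.25% and 61.27%). The 75th percentile of signal ran from 2502.6 to 3296.6 intensity units, and the number of arrays limits the precision. Changes below are log2 differences ± standard error, and positions are those of the array probes on hg18. The words "rose", "fell" and "changed" are used for genes past an adjusted p of 0.05 over 19651 genes.

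The MYC probe tested (chromosome 8, 128822450 to 128822509) was bright in all 5 groups. Its mean lay above the 75th percentile by 6.37 ± 0.15 (SD, n = 4) in empty vector cells and by 5.95 ± 0.12 (SD, n = 4) in those with retinoic acid. It did so by 6.15 ± 0.11 (SD, n = 3) in MycD cells, 5.64 ± 0.05 (SD, n = 4) in MycD cells with retinoic acid and 5.82 ± 0.17 (SD, n = 3) in MycA cells with retinoic acid. The means of the 2 other MYC probes lay between -4.41 and -2.86, so probe levels do not give the abundance of the transcript. Retinoic acid lowered MYC in empty vector cells, where it fell by 0.43 ± 0.09 (adjusted p = 0.00659). In MycD cells MYC fell by 0.52 ± 0.09 with retinoic acid (adjusted p = 0.00251), but 1 of its 2 other probes went the opposite way. The call ended when the probes were averaged (-0.38 ± 0.12, adjusted p = 0.0654) and without MycD replicates 1 and 2 (-0.53 ± 0.14, adjusted p = 0.0672). Between MycD and empty vector cells MYC did not pass without retinoic acid (-0.22 ± 0.09, adjusted p = 0.192). With retinoic acid it was lower in MycD cells by 0.31 ± 0.09 (adjusted p = 0.04), with 1 of its 2 other probes going the opposite way. That call ended when any of 10 arrays was left out and when the probes were averaged (-0.19 ± 0.11, adjusted p = 0.366). Whether these probes lie in sequence carried by the tagged constructs is not given in the sources used here, so the MYC signal does not check the construct labels. PAK2, a kinase, passed in none of the comparisons (0.02 ± 0.07 with retinoic acid in empty vector cells, adjusted p = 0.913). RARA missed the threshold with retinoic acid (0.18 ± 0.06, adjusted p = 0.0703, with its other probe going the opposite way). RARB was not well above background on any array.

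The first comparison asks which genes respond to 4 h of 100 nM retinoic acid in cells without added Myc. DHRS3, which encodes an enzyme that reduces retinaldehyde, rose by 5.33 ± 0.20 (adjusted p = 1.34e-10, n = 4 and 4; chromosome 1, 12550697 to 12550756). TGM2, which encodes transglutaminase 2, was not well above background in empty vector cells and was at least 44.5-fold higher with retinoic acid (chromosome 20, 36199860 to 36199919). The transcriptional repressor HIC1 rose by 4.69 ± 0.14, the chemokine receptor CXCR5 by 4.56 ± 0.19. ID1, an inhibitor of helix-loop-helix transcription factors, rose by 3.50 ± 0.09 (adjusted p = 3.83e-12). The flagellin receptor TLR5 was at least 18.7-fold higher. Of 19651 genes 1311 changed, 846 higher and 465 lower, and 186 genes were over 2-fold higher against 14 over 2-fold lower. The strongest decreases were in SHISA2, which fell by 2.08 ± 0.30, and PID1, which fell by 1.83 ± 0.29. The interleukin 1 decoy receptor IL1R2 fell by 1.77 ± 0.32 (adjusted p = 0.00242), and the glutamate transporter SLC1A3 fell by 1.202 ± 0.151. The plot of 8 genes on each array shows these changes beside the spread of the replicates.

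**Figure D1:**
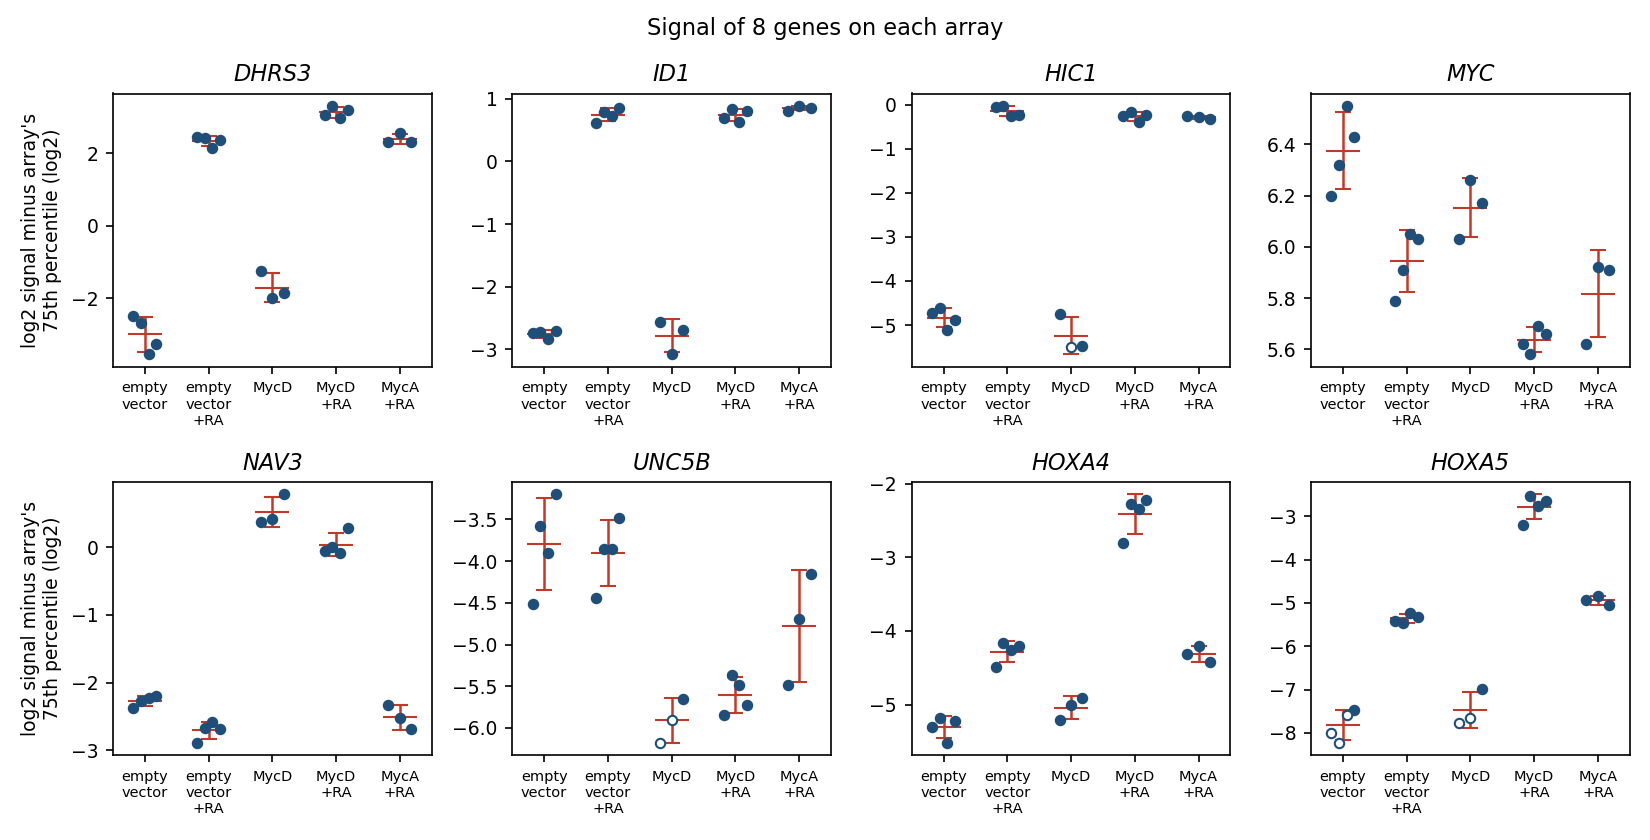
Log2 signal relative to the 75th percentile of each array for DHRS3, ID1, HIC1, MYC, NAV3, UNC5B, HOXA4 and HOXA5 in the 5 groups. Each dot is 1 array, open where the probe was not well above background, and the red bar is the mean ± SD of the 3 or 4 arrays of a group. ID1 was 3.50 higher with retinoic acid in empty vector cells and NAV3 was 2.79 higher in MycD cells.

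Genes known to respond to retinoic acid moved as a group in empty vector cells. Of 25 measured members 14 rose and 1 fell (camera adjusted p = 3.07e-15, or adjusted p = 0.00268 with an estimated correlation). When adjusted over the list alone, 15 rose and 2 fell. They included the ectoenzyme CD38 (2.69 ± 0.14), the ubiquitin ligase subunit ASB2 (2.25 ± 0.14), SMAD3 (0.80 ± 0.07) and, as the 1 that fell, the carnitine transporter SLC22A16, which fell by 0.37 ± 0.07. The median of this list was 0.58, 0.65 and 0.60 on the 3 slides that held both groups. Adhesion and migration genes followed, with 9 of 23 higher and none lower (camera adjusted p = 1.22e-08, or adjusted p = 0.38 with an estimated correlation) or 11 higher when adjusted over the list alone. They included ICAM1 (1.83 ± 0.15), CCR1 (1.246 ± 0.117), ITGA5 (0.91 ± 0.08) and ITGAL (0.60 ± 0.05). Of 34 interferon-response genes 4 rose and 1 fell (camera adjusted p = 0.00614, or adjusted p = 0.654 with an estimated correlation). IRF1 rose by 1.35 ± 0.07 and OASL by 1.14 ± 0.13, while HERC5 fell by 0.42 ± 0.05. Among 31 neutrophil maturation genes 5 rose and 1 fell, including the NADPH oxidase subunit NCF1 (1.85 ± 0.21) and the kinases FGR (1.83 ± 0.17) and LYN (0.57 ± 0.06). That list shifted (camera adjusted p = 0.0296, or adjusted p = 0.895 with an estimated correlation) but not with slide as a block (adjusted p = 0.437), and its median within slides was 0.01, 0.06 and 0.00. Of 27 NF-kappa-B and inflammatory genes 7 rose and 1 fell (camera adjusted p = 0.0252, or adjusted p = 0.707 with an estimated correlation and 0.058 with slide as a block). IER3 rose by 1.61 ± 0.19. Among 20 genes of the BCL2 family and apoptosis 4 rose and 2 fell (camera adjusted p = 0.0474, or adjusted p = 0.38 with an estimated correlation). The changes did not share 1 direction of function. PMAIP1 (0.91 ± 0.09) and BMF (0.59 ± 0.12) promote cell death, while BCL2A1 (0.59 ± 0.08) opposes it. The death ligand TNFSF10 fell by 0.64 ± 0.12.

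Of 46 ribosome biogenesis genes 7 fell with retinoic acid and none rose (camera adjusted p = 1.09e-10, or adjusted p = 0.38 with an estimated correlation). When adjusted over the list alone, 17 were lower. PNO1, a factor of small-subunit assembly, fell by 0.42 ± 0.07, and the median of the list was -0.18, -0.20 and -0.19 within the 3 slides. Of 43 genes activated by Myc 4 fell and none rose (camera adjusted p = 5.65e-06, or adjusted p = 0.654 with an estimated correlation). Of 23 cholesterol synthesis genes 1 fell (camera adjusted p = 0.00023, or adjusted p = 0.664 with an estimated correlation). The other 16 lists did not shift. Their camera adjusted p was 0.459 for retinoid receptors and coregulators, where the coactivator NCOA3 rose by 0.99 ± 0.05. It was 0.436 for genes repressed by Myc, 0.743 for cytosolic ribosomal proteins and 0.264 for promyelocyte and primary granule genes (0.036 with slide as a block). For monocyte and macrophage genes it was 0.436 and for p53 targets 0.754. It was 0.3 for immediate early and stress genes and 0.85 for the unfolded protein and amino acid response, where CEBPB rose by 1.16 ± 0.08. Glycolysis and hypoxia genes had 0.743, with NDRG1 up by 1.06 ± 0.07 and HK2 down by 0.48 ± 0.07. The value was 0.128 for HOX genes and 0.216 for estrogen receptor targets, where AREG fell by 0.90 ± 0.08. For S phase and G2/M genes it was 0.743 and 0.406, and for markers of erythroid, lymphoid and stromal or epithelial cells it was 0.778, 0.743 and 0.743. With slide as a block 1754 genes changed, and 1308 of the 1311 (99.8%) moved the same way on each of the 3 slides with both groups. These genes were selected on the same arrays, which favours such a share. This share and those given below for the other comparisons are therefore no separate evidence.

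The second comparison asks the same of MycD cells. The same genes led it. TGM2 rose by 5.62 ± 0.20, HIC1 by 4.99 ± 0.15, DHRS3 by 4.82 ± 0.22 and CXCR5 by 4.78 ± 0.21 (n = 4 and 3). PALLD, an actin-binding protein, was at least 35.9-fold higher. HOXA5, a homeobox gene, rose by 4.69 ± 0.20 (adjusted p = 9.01e-10; chromosome 7, 27148072 to 27148131). IL1R2 fell by 2.08 ± 0.34, SHISA2 fell by 1.89 ± 0.33 and PID1 fell by 1.84 ± 0.29. In all 1430 genes changed, 898 higher and 532 lower, and 2502 changed with slide as a block. The count was 832 without MycD replicate 2 and 932 without MycD replicate 3, and 1428 of the 1430 genes (99.9%) moved the same way on all 3 slides with both groups. Of the retinoic acid list 15 of 25 rose and 1 fell (camera adjusted p = 1.05e-16, or adjusted p = 0.00173 with an estimated correlation). Within slides the median was 0.63, 0.63 and 0.73. CD38 rose by 2.51 ± 0.15 and ASB2 by 2.21 ± 0.15. Of 46 ribosome biogenesis genes 11 fell (camera adjusted p = 5.62e-16, or adjusted p = 0.211 with an estimated correlation) or 22 adjusted over the list alone. Their median was -0.22, -0.17 and -0.22 within slides. Of 43 genes activated by Myc 5 fell (camera adjusted p = 5.23e-07, or adjusted p = 0.554 with an estimated correlation). Of 34 interferon-response genes 8 rose and 1 fell (camera adjusted p = 0.000437, or adjusted p = 0.445 with an estimated correlation). Of 23 adhesion and migration genes 7 rose (camera adjusted p = 5.12e-06, or adjusted p = 0.445 with an estimated correlation). Of 20 BCL2 family and apoptosis genes 4 rose and 2 fell (camera adjusted p = 0.0236, or adjusted p = 0.211 with an estimated correlation). Cholesterol synthesis genes, 1 of 23 lower (camera adjusted p = 0.000461, or adjusted p = 0.554 with an estimated correlation), also shifted. With slide as a block the neutrophil maturation (adjusted p = 0.0113), inflammatory (0.0313) and erythroid lists (0.0399) shifted up too. Among 11 HOX genes 3 rose (camera adjusted p = 0.000461, or adjusted p = 0.0184 with an estimated correlation), namely HOXA4 (2.63 ± 0.13), HOXA5 and HOXA7 (2.14 ± 0.27).

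The responses of both lines to retinoic acid could be set against each other, because the 2 comparisons share no arrays. Of the 1311 genes that changed in empty vector cells, 958 also changed in MycD cells, all in the same direction. Of these 635 were higher, where independent lists would share 38.7, and 323 lower, where they would share 12.6. Both comparisons used the same estimate of spread per gene, from all 5 groups, and had slides in common. Arrays of different groups on the same slide went together (21 of 24 pairs). The 2 lists are therefore not fully independent, and these expected numbers may be too low. Across the 1311 genes the slope of the response in MycD cells on that in empty vector cells was 0.986, and across all genes, which are not independent replicates, the correlation was 0.693. The interaction of MycD with retinoic acid, which tests the difference between the responses, passed for 2 genes, both neighbours in the HOXA cluster on chromosome 7. HOXA5 rose by 2.46 ± 0.19 in empty vector cells and by 4.69 ± 0.20 in MycD cells, an interaction of 2.23 ± 0.28 (adjusted p = 0.00805, or 0.00363 with slide as a block). Its probe was well above background on only 1 of 4 empty vector and 1 of 3 MycD arrays without retinoic acid, so these responses start from a level mostly near background and their sizes are uncertain. HOXA4 (27134719 to 27134778) rose by 1.03 ± 0.12 and by 2.63 ± 0.13, an interaction of 1.60 ± 0.18 (adjusted p = 0.00435, or 0.00394 with slide as a block). HOXA5 lost its call without MycD replicate 2 (2.14 ± 0.30, adjusted p = 0.0508) and with quantile normalization (2.94 ± 0.54, adjusted p = 0.424). It also lost it with the description number and slide together as blocks (2.19 ± 0.23, adjusted p = 0.0798). Both lost it without MycD replicates 1 and 2 together (1.75 ± 0.31 and 1.47 ± 0.23, adjusted p = 0.306 and 0.191). HOXA7, on the same stretch, had an interaction of 1.27 that did not pass (adjusted p = 1). As a list, HOX genes had a larger response in MycD cells (median 0.519, camera adjusted p = 2.71e-07, or adjusted p = 0.00111 with an estimated correlation). That median was 0.263 with normexp and 0.376 in the series matrix values. In the list 3 of 11 passed when adjusted over the list alone. The plot of both responses shows the shared genes along the diagonal.

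**Figure D2:**
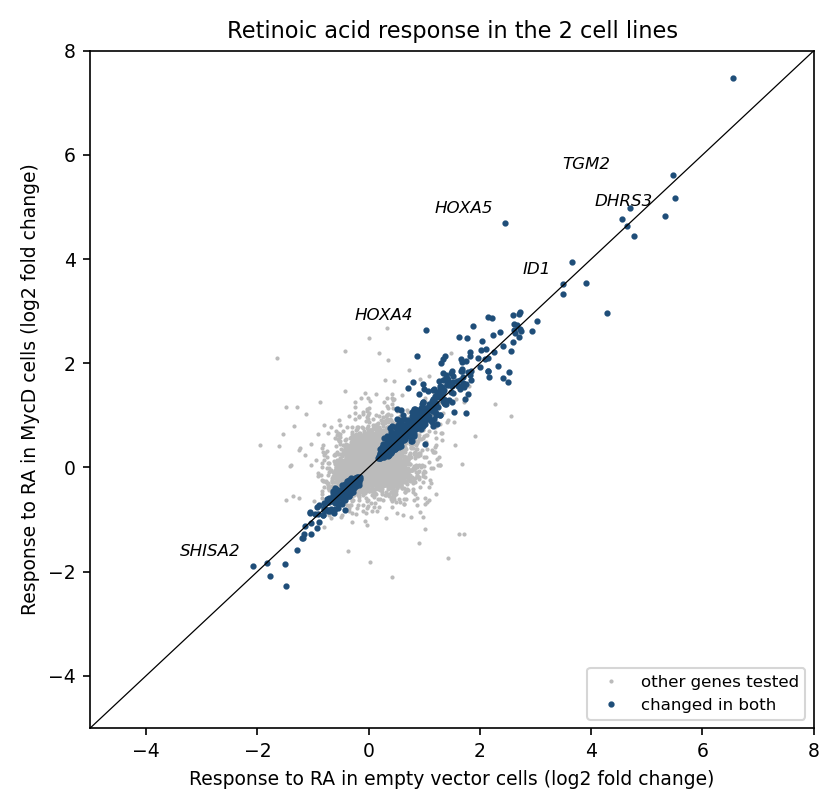
Log2 change with retinoic acid in empty vector cells (horizontal) and in MycD cells (vertical) for 19651 genes, with a diagonal line for equal changes. The 958 genes in blue changed in both and moved the same way, with a slope of 0.986 over the 1311 genes changed in empty vector cells, and HOXA4 and HOXA5 lie above the line.

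The third comparison asks what differs between MycD and empty vector cells without retinoic acid. BMP2, a secreted growth factor, rose by 3.01 ± 0.26 in MycD cells (adjusted p = 4.28e-06, n = 3 and 4; chromosome 20, 6707242 to 6707301), and NAV3 rose by 2.79 ± 0.12 (adjusted p = 4.36e-09; chromosome 12, 77130327 to 77130386). IGFBP2, which binds insulin-like growth factors, rose by 3.08 ± 0.41, the secreted hormone STC2 by 2.77 ± 0.28 and the cytochrome P450 CYP2S1 by 2.85 ± 0.22. The peroxisomal reductase PECR, not well above background in empty vector cells, was at least 8.35-fold higher. The netrin receptor UNC5B fell by 2.11 ± 0.32 (adjusted p = 0.000907), a call lost without MycD replicates 1 and 2 (-1.85 ± 0.49, adjusted p = 0.0846). CLUHP3, a pseudogene, fell by 1.37 ± 0.19. In all 1388 genes changed, 822 higher and 566 lower, and among changes over 2-fold 164 genes were higher and 17 lower. Of 27 inflammatory genes 9 rose and none fell (camera adjusted p = 1.36e-09, or adjusted p = 0.228 with an estimated correlation). Adjusted over the list alone, 11 were higher and 1 lower. TNFAIP6 rose by 1.68 ± 0.20, PTGS2, the inducible cyclooxygenase, by 1.09 ± 0.20, ICAM1 by 1.05 ± 0.17, the chemokine CCL5 by 0.90 ± 0.12 and the interleukin 1 antagonist IL1RN by 0.56 ± 0.07. Of 24 immediate early and stress genes 4 rose (camera adjusted p = 0.00156, or adjusted p = 0.228 with an estimated correlation), with JUN at 1.11 ± 0.18. Of 20 p53 targets 4 rose and 1 fell (camera adjusted p = 0.0113, or adjusted p = 0.228 with an estimated correlation), with GADD45A at 0.74 ± 0.09.

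Among myeloid genes 2 lists were called in MycD cells. Of 21 monocyte and macrophage genes 6 rose and 1 fell (camera adjusted p = 0.00156, or adjusted p = 0.58 with an estimated correlation), including SPP1, which encodes osteopontin (2.55 ± 0.42), and the matrix proteoglycan VCAN (1.75 ± 0.18). Of 31 neutrophil maturation genes 4 rose (camera adjusted p = 9.83e-06, or adjusted p = 0.58 with an estimated correlation) or 10 adjusted over the list alone. Both calls were kept with slide as a block (adjusted p = 0.0153 for monocyte and 0.00249 for neutrophil genes), but the direction differed between slides. The median was 0.46 for neutrophil and 0.28 for monocyte genes on slide 1, but -0.15 and -0.07 on slide 3, the only other slide with both groups. On the same slides the inflammatory list had medians of 0.49 and 0.06, the immediate early list 0.28 and 0.02, and the p53 list 0.11 and 0.02. Of 43 genes activated by Myc 2 fell, with a median of -0.09, or -0.05 with quantile normalization (camera adjusted p = 0.00599, or adjusted p = 0.739 with an estimated correlation). The call ended with slide as a block (adjusted p = 0.141), and their median was -0.11 on slide 1 and 0.05 on slide 3. Cytosolic ribosomal proteins shifted down with no member passing (camera adjusted p = 0.00461, or adjusted p = 0.739 with an estimated correlation). Their median was -0.084, or -0.003 with quantile normalization, under which no list was called lower in this comparison. G2/M genes shifted up with 1 of 31 passing (camera adjusted p = 0.00418, or adjusted p = 0.58 with an estimated correlation). So did glycolysis and hypoxia genes (2 of 26, camera adjusted p = 0.0289, or adjusted p = 0.58 with an estimated correlation), among them the glucose transporter SLC2A3 (1.06 ± 0.13). Retinoid receptors and coregulators shifted up by a median of 0.05, or 0.08 in the series matrix values (camera adjusted p = 0.0366, or adjusted p = 0.58 with an estimated correlation) but not with slide as a block (adjusted p = 0.0549). With slide as a block 1735 genes changed, and 1386 of the 1388 (99.9%) moved the same way on both slides with the 2 groups. Without MycD replicate 3 the count was 790, and without MycD replicates 1 and 2 it was 329.

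The fourth comparison asks what differs between MycD and empty vector cells in the presence of retinoic acid. IGFBP2 rose by 3.22 ± 0.38 (adjusted p = 6.84e-05, n = 4 and 4), PECR by 3.06 ± 0.15 and STC2 by 2.81 ± 0.26. CPNE8, a calcium-dependent membrane-binding protein, was at least 8.01-fold higher. HOXA5 was higher by 2.57 ± 0.19 and HOXA4 by 1.87 ± 0.12 (adjusted p = 2.81e-07). UNC5B fell by 1.70 ± 0.30, and ITPR3, a calcium channel of the endoplasmic reticulum, fell by 1.36 ± 0.22. In all 1560 genes changed, 962 higher and 598 lower, with 2188 under the slide block. The count was 939 without the fourth replicate of MycD with retinoic acid, 992 without the second of empty vector with retinoic acid and 962 without the third. Of these genes 1533 (98.3%) moved the same way on all 3 slides with both groups. Of 27 inflammatory genes 11 rose and none fell (camera adjusted p = 4.5e-09, or adjusted p = 0.156 with an estimated correlation) or 14 adjusted over the list alone. Their median within slides was 0.32, 0.24 and 0.41. TNFAIP6 rose by 1.91 ± 0.18, PTGS2 by 1.01 ± 0.19 and CCL5 by 0.81 ± 0.11. Of 20 p53 targets 6 rose (camera adjusted p = 0.000645, or adjusted p = 0.0761 with an estimated correlation), with medians within slides of 0.19, 0.15 and 0.21. GADD45A rose by 0.77 ± 0.09 and SESN2 by 0.63 ± 0.12. Of 31 neutrophil maturation genes 7 rose (camera adjusted p = 6.84e-06, or adjusted p = 0.555 with an estimated correlation). Of 21 monocyte and macrophage genes 7 rose and 1 fell (camera adjusted p = 0.00198, or adjusted p = 0.555 with an estimated correlation). Both lists had medians above 0 on each of the 3 slides here, at 0.45, 0.25 and 0.55 and at 0.51, 0.29 and 0.39. The formyl peptide receptor FPR2 rose by 1.47 ± 0.23, SPP1 by 2.43 ± 0.39 and the phagocytic receptor MERTK by 1.204 ± 0.211. Of 22 promyelocyte genes 2 rose and 3 fell, and the list did not shift (camera adjusted p = 0.325). The protease PRTN3 fell by 0.47 ± 0.08 and the receptor FLT3 by 0.42 ± 0.08, while DEFA4 rose by 1.66 ± 0.43 and GFI1 by 0.28 ± 0.05. Of 11 HOX genes 3 rose (camera adjusted p = 0.000314, or adjusted p = 0.0235 with an estimated correlation). Immediate early genes shifted up, 4 of 24 higher and 1 lower (camera adjusted p = 0.000989, or adjusted p = 0.147 with an estimated correlation), as did G2/M genes, 3 of 31 higher (camera adjusted p = 0.000989, or adjusted p = 0.555 with an estimated correlation). The retinoic acid list also shifted up, 5 of 25 higher (camera adjusted p = 0.0284, or adjusted p = 0.512 with an estimated correlation), and so did genes repressed by Myc, 4 of 19 higher and 1 lower (camera adjusted p = 0.013, or adjusted p = 0.41 with an estimated correlation). Genes activated by Myc shifted down, 4 of 43 lower (camera adjusted p = 0.00019, or adjusted p = 0.625 with an estimated correlation). Ribosome biogenesis genes did too, 1 of 46 lower (camera adjusted p = 0.007, or adjusted p = 0.787 with an estimated correlation).

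The changes in MycD cells without and with retinoic acid come from different arrays. Of the 1388 genes changed without it, 948 also changed with it, all in the same direction. Of these 639 were higher, where independent lists would share 40.2, and 309 lower, where they would share 17.2. Here too the spread per gene and some slides were shared between the comparisons, so these expected numbers may be too low. The slope across the 1388 genes was 0.905, and across all genes the correlation was 0.652.

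The fifth comparison asks what differs between MycA and empty vector cells in the presence of retinoic acid, and few genes passed. The zinc finger gene HIVEP2 rose by 1.57 ± 0.21 (adjusted p = 0.00859, n = 3 and 4; chromosome 6, 143114544 to 143114603), and the receptor tyrosine kinase gene ROR2 rose by 1.01 ± 0.13 (adjusted p = 0.00859). The glycosyltransferase GALNT14 fell by 1.22 ± 0.10 (adjusted p = 9.89e-05; chromosome 2, 30986874 to 30986933). CASP2 fell by 0.50 ± 0.07 (adjusted p = 0.0157), a call lost without replicates 2 or 4 of empty vector with retinoic acid (adjusted p = 0.0518 and 0.0875) and without replicates 1 or 2 of MycA (adjusted p = 0.122 and 0.0845). ROR2 lost its call without replicate 2 of MycA (0.98 ± 0.15, adjusted p = 0.0508). LAMP5 fell by 0.56 ± 0.09 (adjusted p = 0.0475) and lost its call when any of 16 arrays was left out, with an adjusted p of up to 0.145 without the third replicate of empty vector with retinoic acid. The sixth was a transcript without a gene symbol on chromosome 11 (THC2611974, 57001490 to 57001549), higher by 0.90 ± 0.10 (adjusted p = 0.00284) and named after its value was seen. In all 6 of 19651 genes changed in limma, 3 higher and 3 lower, against 882 at an unadjusted p under 0.05, and 7 changed with slide as a block. None passed with only the groups compared, or with the description number and slide together as blocks. In these settings HIVEP2 had an adjusted p of 1 and 0.118 and GALNT14 of 0.275 and 0.0517. All 6 moved the same way on the 3 slides with both groups. No member of any of the 25 lists passed, also adjusted over the list alone, while camera called 9 lists with small medians. Shifted up were inflammatory genes (median 0.11, camera adjusted p = 3.54e-06, or adjusted p = 0.472 with an estimated correlation) and p53 targets (median 0.10, camera adjusted p = 0.00156, or adjusted p = 0.0751 with an estimated correlation). HOX genes (median 0.02, camera adjusted p = 0.00355, or adjusted p = 0.0673 with an estimated correlation) and interferon-response genes (median 0.03, camera adjusted p = 0.0112, or adjusted p = 0.913 with an estimated correlation) shifted up too. So did neutrophil maturation, cholesterol synthesis and G2/M genes, with medians of 0.11, 0.03 and 0.03 (camera adjusted p = 0.0112, 0.0195 and 0.0427, or adjusted p = 0.913 with an estimated correlation for all 3). Genes activated by Myc (median -0.05, camera adjusted p = 0.00708, or adjusted p = 0.913 with an estimated correlation) and cytosolic ribosomal proteins (median -0.04, camera adjusted p = 0.0195, or adjusted p = 0.925 with an estimated correlation) shifted down. In the series matrix values these 2 medians were -0.03 and 0.00, and with quantile normalization that of HOX genes was 0.04. The p53 median was 0.08, 0.10 and 0.08 within slides, the inflammatory median 0.18, 0.24 and 0.01. The direction differed between slides for neutrophil genes (0.02, 0.26 and -0.02), cholesterol synthesis genes (-0.03, 0.07 and 0.21) and cytosolic ribosomal proteins (-0.13, -0.01 and 0.10). It also differed for interferon-response genes (0.02, 0.11 and -0.04) and genes activated by Myc (-0.10, -0.07 and 0.03). With slide as a block only the ribosomal protein call ended (adjusted p = 0.156). The neutrophil (0.0203), cholesterol (2.21e-05), interferon (0.0435) and Myc-activated (0.0189) calls were kept, and monocyte and macrophage genes (0.0428) and immediate early genes (0.0197) passed. The number of lists was 5 without the third replicate of empty vector with retinoic acid and 3 without the first of MycA.

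The genes that differed between MycD and empty vector cells without retinoic acid were followed in this comparison, which uses other arrays. Of the 1388, 1013 (73%) moved the same way in MycA cells, 616 of 822 upward and 397 of 566 downward, with a slope of 0.152. Chance could not be excluded, since 5 of 35 splits of the arrays, the real one included, gave as high a share. Within the slides 66.3%, 61.1% and 59.2% moved the same way. Of the 6 genes changed in MycA cells, 4 also changed with MycD, all in the same direction. The spread per gene and some slides were shared here too, so this overlap is not fully independent.

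**Figure D3:**
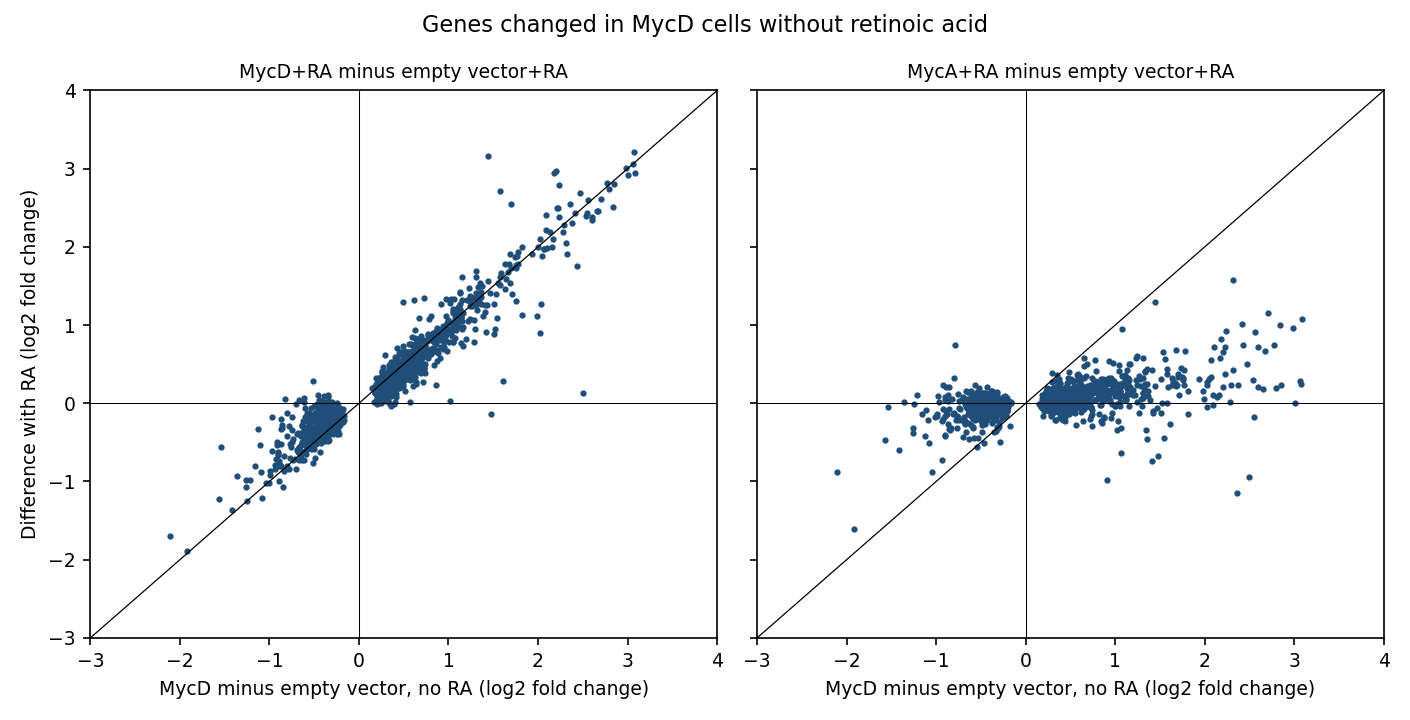
The 1388 genes changed in MycD against empty vector cells, with that log2 change on the horizontal axis and, on the vertical axes, their log2 change in MycD against empty vector cells with retinoic acid (slope 0.905) and in MycA against empty vector cells with retinoic acid (slope 0.152). In the second panel 73% of the genes moved the same way as in MycD cells, a share reached by 5 of 35 splits of the arrays, the real one included.

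The sixth comparison sets MycD against MycA, both with retinoic acid. FERMT1, which encodes an integrin-binding protein, was not well above background in MycA cells and was at least 12.9-fold higher in MycD cells (adjusted p = 9.59e-05, n = 4 and 3; chromosome 20, 6003830 to 6003889). NAV3 was higher by 2.55 ± 0.12 (adjusted p = 1.63e-08), IGFBP2 by 2.97 ± 0.41, SPP1 by 2.61 ± 0.42 and STC2 by 2.07 ± 0.28, and BMP2 was at least 7.59-fold higher. HOXA5 was higher by 2.16 ± 0.20 and HOXA4 by 1.897 ± 0.132. The gene TEX15 fell by 1.36 ± 0.19 and the sugar phosphate transporter SLC37A1 fell by 0.76 ± 0.09. In all 691 genes changed, 498 higher and 193 lower, with 1006 under the slide block, and all 691 moved the same way on both slides that held the groups. The count was 427 without replicate 4 of MycD with retinoic acid and 352 and 345 without replicates 2 and 3 of MycA. Of 27 inflammatory genes 5 were higher in MycD cells and none lower (camera adjusted p = 0.000338, or adjusted p = 0.545 with an estimated correlation) or 9 higher and 1 lower adjusted over the list alone. They included TNFAIP6 (1.23 ± 0.20) and IL1RN (0.45 ± 0.07). Neutrophil maturation genes shifted up, 2 of 31 higher (camera adjusted p = 0.0021, or adjusted p = 0.805 with an estimated correlation). Monocyte and macrophage genes did too, 3 of 21 higher (camera adjusted p = 0.0344, or adjusted p = 0.805 with an estimated correlation), with VCAN at 0.97 ± 0.18. The medians of these 3 lists were above 0 on both slides with the 2 groups, at 0.11 and 0.22, 0.22 and 0.31, and 0.11 and 0.19. Immediate early genes shifted up, 2 of 24 higher (camera adjusted p = 0.0344, or adjusted p = 0.545 with an estimated correlation and 0.052 with slide as a block). The retinoic acid list did too, 4 of 25 higher (camera adjusted p = 0.0403, or adjusted p = 0.545 with an estimated correlation). Genes repressed by Myc followed, 2 of 19 higher (camera adjusted p = 0.042, or adjusted p = 0.545 with an estimated correlation and 0.0553 with slide as a block), and so did G2/M genes, 3 of 31 higher (camera adjusted p = 0.042, or adjusted p = 0.805 with an estimated correlation). HOX genes shifted up with a median of 0.07 and 3 of 11 higher (camera adjusted p = 0.0458, or adjusted p = 0.545 with an estimated correlation and 0.13 with slide as a block), and that median was -0.01 in the deposited series matrix values. Genes activated by Myc and ribosome biogenesis genes (both camera adjusted p = 0.0344, or adjusted p = 0.805 with an estimated correlation) shifted down with no member passing. So did S phase genes with 1 of 30 lower (camera adjusted p = 0.0403, or adjusted p = 0.805 with an estimated correlation), though their median was -0.01 and 0.01 within slides. Of these 11 lists, 1 was called without replicate 1 of MycD with retinoic acid, 7 without its replicate 2, 5 without replicate 2 of MycA and 0 without replicate 3 of MycA.

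**Figure D4:**
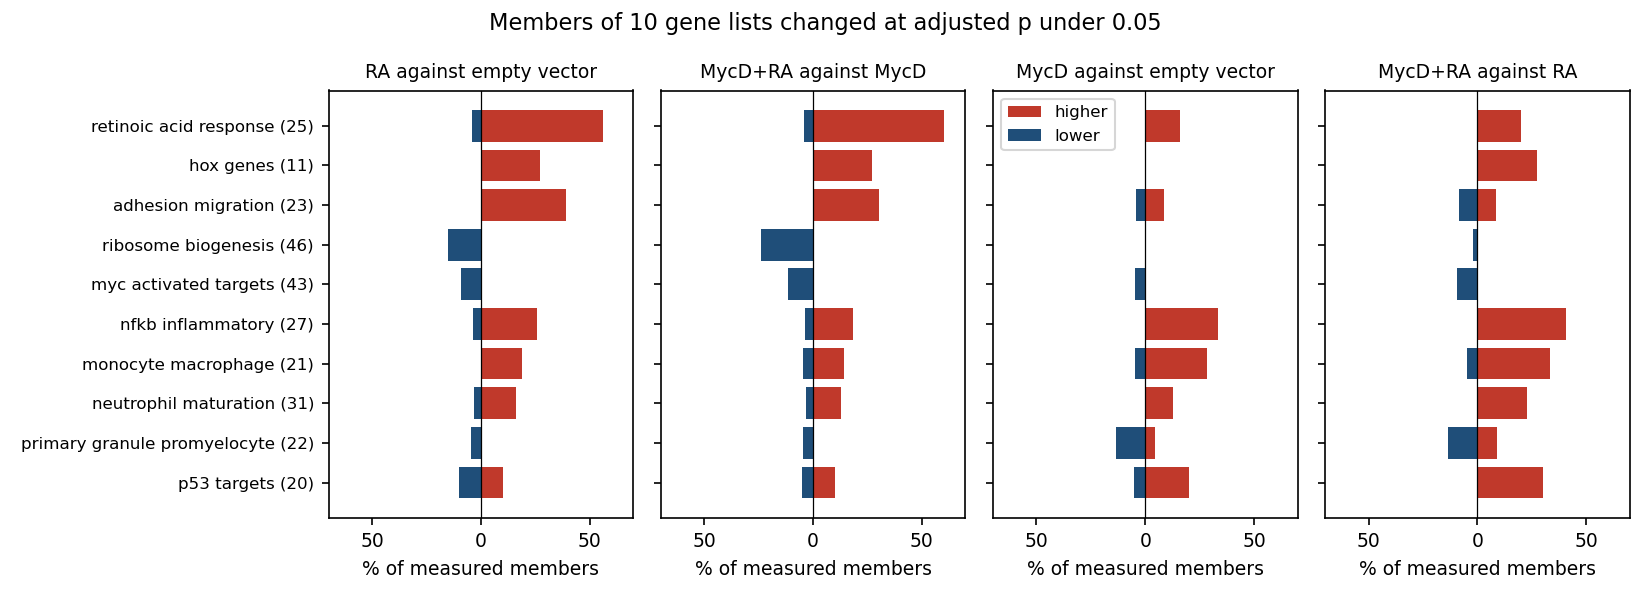
Percent of the measured members of 10 gene lists that were higher (right) or lower (left) past the threshold in 4 comparisons. Of 25 retinoic acid response genes 14 rose with retinoic acid in empty vector cells, and of 27 inflammatory genes 9 rose in MycD cells.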

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

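The tests of HOXA4 and HOXA5, the test of MycD cells mixed into the MycA samples, the splits with the line difference taken out, and those of dim probes, array scaling and MycD replicates 1 and 2 were chosen only after the results were seen. The other splits of the arrays and the shares within slides were set before.

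Other splits of the arrays between the same groups were counted for each comparison. For retinoic acid in empty vector cells, MycD against empty vector, retinoic acid in MycD cells, MycD with retinoic acid against empty vector with it, MycA against empty vector with retinoic acid, and MycD against MycA, only 1 of 35 splits, the real one, called as many genes. No share under 1 of 35 can be reached, and the comparisons share arrays. Chance is therefore argued against only as far as these splits go. They exchange arrays between slides, although arrays of the same slide went together (21 of 24 pairs). For MycA the real count is small and was 0 with only the groups compared and with the description number and slide as blocks. Chance is therefore not excluded for MycA. The real counts were 1311, 1388, 1430, 1560, 6 and 691, and the highest of the other splits were 1, 400, 347, 0, 1 and 274. The split of 400 set slides 1, 4 and 5 against slides 1, 2 and 3. That of 274 set slides 1, 3 and 5 against slides 2 and 4, with MycD and MycA arrays on both sides. Differences between slides can thus enter such counts, and the real groups were also spread unevenly over the slides. For the interaction, 4 of 100 splits called at least the 2 genes of the real one, and the highest of the others called 793. These splits exchange MycD and empty vector arrays, so the difference between the lines enters the interaction. With each gene's average difference between the lines taken out, the split of 793 genes called 0. Only 1 of the 100 splits, the real one, then called 2 genes and the highest other called 1. So small a margin does not exclude chance, since the real count was itself 1 with quantile normalization and without MycD replicate 2. The line difference was also estimated with the real groups, and these splits too exchange arrays between slides.

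HOXA4 and HOXA5 stood out by a test of the difference between the responses to retinoic acid, with interactions of 1.60 ± 0.18 and 2.23 ± 0.28. A general gain of the response in MycD cells is argued against, since the slope over the other responding genes was 0.979 while the 2 genes responded 2.56 and 1.91 times as strongly. Differences between slides are also argued against, because at least 95.5% of either interaction was kept with slide as a block. A floor that hides the response in empty vector cells is argued against for HOXA4, which was well above background on all 18 arrays. For HOXA5 it cannot be told apart from a real difference in response, since only 2 of 7 untreated arrays were well above background. The interaction tests whether the lines differ in their response, and what could cause such a difference at this cluster was not tested.

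The share of MycD-changed genes that moved the same way in MycA cells was 73%. Chance could not be excluded, since 5 of 35 splits of the 7 arrays gave as high a share and the highest other gave 82%. Differences between slides cannot be told apart from a shift in MycA cells. On the slide with the lowest share 59.2% moved the same way, but each slide sets 1 array against 1, and the bound of 55% set before allowed for no such spread. MycD cells or RNA mixed into the MycA samples cannot be told apart either. With the best share of 10.13%, 9.4% of the genes lay more than 2 standard errors from their predicted shift, against 5% of the genes not changed by MycD. That ratio of 1.88 was reached in 4 of the 35 splits, up to 2.43. A partial activity of MycA was not tested.

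Among genes changed over 2-fold in MycD cells 164 were higher and 17 lower (90.6% higher). A test set before, the share of the higher genes well above background on every MycD array (137 of 164), decides nothing because the filter kept such genes. A raised floor of dim probes is argued against by the probes well above background on all 18 arrays, where 98 genes were higher and 5 lower (95.1% higher). Of the 164, 156 were also higher with MycD in the presence of retinoic acid. Scaling is argued against by quantile normalization, which gave 88%, and weak signal on MycD replicates 1 and 2 by leaving them out, which gave 96.6%. The asymmetry was not particular to MycD against empty vector cells. Over 2-fold, 186 genes were higher and 14 lower with retinoic acid in empty vector cells, 201 and 14 with it in MycD cells, 165 and 13 for MycD with retinoic acid against empty vector with it, and 118 and 7 for MycD against MycA. Its cause stays open, and no biological explanation was tested.

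The response of 5 lists to retinoic acid differed between MycD and empty vector cells, by the test of the difference. HOX genes had a median difference of 0.519 (camera adjusted p = 2.71e-07; 0.00111 with an estimated correlation), which was 0.263 with normexp and 0.376 in the series matrix values. Lymphoid markers had one of 0.178 (0.0249; 0.326 with an estimated correlation), or 0.102 with normexp. Cytosolic ribosomal proteins differed by 0.056 (0.0249; 0.945 with an estimated correlation), which turned to -0.01 with quantile normalization, ribosome biogenesis genes by -0.028 (0.0149; 0.945 with an estimated correlation) and retinoid receptors and coregulators by -0.016 (0.0149; 0.945 with an estimated correlation; 0.103 with slide as a block). With quantile normalization the last 2 medians were -0.049 and -0.042. In that setting only 1 list was called higher, against 3 in the reported fit. No lymphoid, ribosomal, ribosome biogenesis or receptor gene passed on its own. The number of these lists was 2 without empty vector replicate 1, MycD replicate 3, replicate 1 of MycD with retinoic acid or replicate 3 of empty vector with retinoic acid, and 3 without replicate 4 of the latter.

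In groups of 4 arrays, 1 array lay far from the other 3 in 15 of the 159 groups of values tested, where chance gives about 1 in 20. Empty vector replicate 1 had TENT5C at -2.35 (others -1.88 to -1.79), ATP8A2 at -5.62 (others -6.55 to -6.50), MACC1 at -6.17 (others -5.68 to -5.66) and RARA at 0.70 (others 0.89 to 0.91). In empty vector cells with retinoic acid, replicate 1 had BMP2 at -7.85 (others -6.80 to -6.64), PTCH1 at -6.46 (others -5.67 to -5.61), ROR2 at -2.52 (others -2.82 to -2.78) and 65.39% of spots well above background (others 71.73% to 73%). In MycD cells with retinoic acid, replicate 3 had TGM2 at -2.22 (others -1.69 to -1.60), LILRA5 at -1.83 (others -1.50 to -1.46) and PAK2 at 1.77 (others 1.94 to 1.96). Replicate 1 of that group had IGFBP2 at -1.89 (others -0.72 to -0.66) and FERMT1 at -4.57 (others -3.50 to -3.42), and replicate 2 had MREG at -3.19 (others -5.14 to -4.90) and NIBAN3 at -4.65 (others -5.34 to -5.29).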

How the results depend on the processing

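All alternatives were chosen before the data were examined except 1: leaving out MycD replicates 1 and 2 together was chosen after they were seen to have the fewest spots well above background. Counts below follow the order of retinoic acid in empty vector cells, MycD against empty vector, retinoic acid in MycD cells, MycD with retinoic acid against empty vector with it, MycA against empty vector with retinoic acid, MycD against MycA, and the interaction, where the reported counts were 1311, 1388, 1430, 1560, 6, 691 and 2 genes and 9, 10, 8, 11, 9, 11 and 5 lists. Where no cause is named, the cause was not tested.

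Normexp background correction lowered the first 4 counts to 812, 777, 835 and 883, and the series matrix values gave 805, 823, 869 and 938 and, for MycD against MycA, 424. Quantile normalization, the filter for probes above background on every array and leaving out MycD replicates 1 and 2 each gave 1 gene for the interaction. With the last of these it was a lower gene that was not among the 2 reported. That setting also gave 329 genes for MycD against empty vector and 488 for retinoic acid in MycD cells, with 1 MycD array left that is assumed to vary like the other groups, so fewer samples entered. Fitting only the groups compared, with fewer arrays to estimate the spread, gave 605, 690, 900, 0 and 214 genes from the second to the sixth comparison. Array weights gave 2154, 4223, 3494, 2401, 33, 2380 and 6, with weights of 4.363 for MycD replicate 3 and 3.812 for MycA replicate 2 and at most 1.88 for the others. Among the other scalings, the share of higher genes moved by over 10 points with normexp, to 69.2% for MycD against empty vector (59.2% reported) and to 66.7% for the few MycA genes (50% reported). Quantile normalization gave 52.8% for retinoic acid in MycD cells (62.8% reported). Larger moves came without MycD replicates 1 and 2, to 84.5% for MycD against empty vector and 74% for retinoic acid in MycD cells. For MycD against MycA (72.1% reported) it was 88.3% with only the groups compared and 55.3% with array weights, and for retinoic acid in empty vector cells (64.5% reported) 51.8% with the description number and slide together. Leaving the dim probes in and averaging the probes of a gene kept each count within 1.5 times.

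Arrays with the same replicate number went together in part, but number and slide overlap. Of 32 pairs with the same number in the sample description 18 had deviations correlated over 0.1 (median 0.16, against -0.03 for other pairs). Of 33 with the same number in the title 16 had (median 0.06, against -0.01). Of 18 arrays 11 correlated best with an array of their own description number. Arrays on the same slide went together more often (21 of 24 pairs, median 0.30, against -0.09 for other pairs). The 16 pairs with the same description number and slide had a median of 0.30, and the 8 with only the same slide had 0.26. The 16 with the same number on different slides had -0.10, so these correlations did not show the number pairing arrays beyond the slide. The block counts leave this open. With the description number added to slide as a block, the count rose from 1754 to 2828 in the first comparison and from 2502 to 2822 in the third. It fell from 1735 to 1597 in the second, 2188 to 2109 in the fourth, 7 to 0 in the fifth and 1006 to 963 in the sixth. With the description number as a replicate block the counts of the first 6 comparisons were 2348, 2223, 2295, 2612, 20 and 1565, with the title number 1981, 17 and 1173 for the first, the fifth and the sixth, and with the description number and slide together 2828, 2822 and 0 for the first, the third and the fifth. Slide as a fixed block gave 2502 for retinoic acid in MycD cells, and slide as a random block gave 2150, 2239, 2650, 2575, 22 and 1256.

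An estimated correlation between genes left 1, 0, 2, 1, 0, 0 and 1 lists. Fry, which tests whether a list moves one way and not whether it differs from other genes, gave 4 lists for MycD against empty vector, 0 for MycA, 1 for MycD against MycA and 1 for the interaction. Without MycD replicates 1 and 2 the interaction had 10 lists.

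With each array left out in turn the counts ran from 881 (empty vector 2) to 1523, 790 (MycD 3) to 1516, 832 (MycD 2) to 1522, 939 (MycD with retinoic acid 4) to 1805, 4 (empty vector with retinoic acid 4) to 9, 345 (MycA 3) to 772, and 1 (MycD 2) to 3 genes. Lists ran from 6 to 9, 7 to 12, 8 to 11, 10 to 13, 3 (MycA 1) to 11, 0 (MycA 3) to 12, and 2 to 7.

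Of 442 calls of genes that were named or belonged to a list, 193 were kept in every setting that tested them and 249 were lost in at least 1. Of the 7956 values with 1 array left out, 975 lost the call. The log2 fold change of BCL2, MycD+RA against RA, was -0.35 (adjusted p = 0.000325) and reversed to 0.03 ± 0.17 when all probes of a gene were averaged (adjusted p = 0.961), while its other alternatives with all arrays gave adjusted p of 3.76e-05 to 0.00835. Signal over background limits what could be seen on MycD replicates 1 and 2, where the fewest spots were well above background (61.27% and 61.25%).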

Other observations

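The probes without a gene symbol in the table were looked up by their position only after the results were seen, and nothing was tested on them beyond the comparisons reported. With retinoic acid in empty vector cells THC2668815 (chromosome 9, 131540357 to 131540510) was higher by 6.54 ± 0.37, at 821 bp from the probe of PTGES, which was itself higher by 2.14, and in MycD cells it was higher by 7.48 ± 0.40. A_32_P75141 (chromosome 1, 12600244 to 12600303) was higher by 4.76 ± 0.18, at 49488 bp from the DHRS3 probe, and THC2651958 (chromosome 4, 15463102 to 15463161) by 2.74 ± 0.16, at 3760 bp from the CD38 probe. In MycD against empty vector cells, both with retinoic acid, BX097190 (chromosome 3, 141778788 to 141778847) was higher by 2.39 ± 0.18, at 9660 bp from the probe of CLSTN2, which was higher by 1.88.

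Along the HOXA cluster on chromosome 7, group means relative to the 75th percentile differed by probe, and levels of different probes do not compare their genes. For HOXA3 the probe at 27116444 to 27116503 lay between 6.66 and 6.85 in all groups. Its other probe (27113296 to 27113355) lay between -9.12 and -7.44 and was well above background on 1 of the 18 arrays. HOXA6 (27153558 to 27153617) had its highest mean in MycA cells with retinoic acid (-5.69, well above background on 3 of 3 arrays). It had -6.70 in MycD cells with it (2 of 4) and -7.28 in empty vector cells with it (3 of 4). Without it the means were -7.22 in empty vector and -7.05 in MycD cells. HOXA7 (27160956 to 27161015) had means of -7.23 in empty vector cells, -7.41 in MycD cells, -6.35 in empty vector cells with retinoic acid, -5.27 in MycD cells with it and -6.36 in MycA cells with it. HOXA9 (27169113 to 27169172), too dim for the tests, was well above background on 2 of 3 MycD arrays and 3 of 4 arrays of MycD with retinoic acid, on 1 of 3 of MycA, and on none of the 8 empty vector arrays.

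The median, mean and test of a list differed in sign for 7 of the 25 lists with retinoic acid in empty vector cells, 7 in MycD against empty vector, 3 with retinoic acid in MycD cells, 4 for MycD with retinoic acid against empty vector with it, 6 for MycA, 4 for MycD against MycA and 5 for the interaction, and none of these lists was among those that shifted.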
